A study of Mus musculus with 11 samples.

How the data were processed

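RNA of articular cartilage from 11 mouse knees was measured: 4 contralateral and 3 DMM knees of c-FosWT mice and 4 DMM knees of c-FosDCh mice, all taken 4 weeks after surgery. Per the labels' protocols, cartilage was dissected with a scalpel, RNA was isolated with TRI Reagent, poly(A) RNA was selected, directional libraries were made with a NEBNext Ultra II kit, and single reads were sequenced on a NextSeq500. Per the submitters' processing notes, bcl2fastq 2.19.1.403, STAR 2.6.1a, RSEM with no version, DESeq2 1.22.2 and the mouse build GRCm38 were used; what RSEM was used for, the annotation release and the strand column taken are not given in the sources used here. The labels' protocols name DESeq2 with an adjusted p threshold of 0.05 for the authors' own test.

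The deposited values are raw counts per gene, 1 file per library, in the layout that STAR writes, with 55421 genes and 4 read classes that are not genes. The read classes stayed out of library sizes and tests. As percent of the reads in the deposited files they ranged from 7.33 to 26.33 for unmapped, 6.79 to 10.19 for multimapping, 33.18 to 41.97 for no feature and 0.62 to 0.94 for ambiguous reads, which left 33.08 to 43.16% as gene counts. Gene counts per library ranged from 13593454 to 18280558 with a median of 16387548. Mitochondrially encoded genes held 0.546 to 1.96% of gene counts, the 3 genes Gm26917, Gm42418 and Gm23935 held 7.24 to 14.67%, and the 10 most abundant genes of a library held 17.69 to 25.71%. Symbols and coordinates came from GENCODE M21 (GRCm38) by unversioned identifier, which matched 55154 genes, 54587 of them with the same version. Of 477 genes whose exons lie wholly inside exons of the other strand, 253 had at least 1 count and 22 had at least 110 counts summed over the libraries; since the strand column is not stated, counts of genes overlapped by an antisense gene are uncertain, as are those of genes with close copies. No pair of libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom was 31.03 over genes with a summed count of at least 20. Each library was therefore 1 replicate. The c-FosDCh DMM libraries were numbered by accession order, since 2 of them carry the same number; their titles name 4 different animals.

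Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 18125 genes, TMM scaled the libraries, and all 11 libraries entered 1 quasi-likelihood fit (glmQLFit with robust = TRUE, glmQLFTest) with group as the only term. This gave a common biological coefficient of variation of 0.315. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were the absolute log2 fold change divided by the square root of F. Tests were two-sided. CPM were computed from these counts and TMM-scaled totals, with a prior count of 2 on the log2 scale, and ± stands for the SD of CPM or of a score and for the SE of a log2 fold change. The alternatives used limma 3.58.1 and DESeq2 1.42.0. Files were read with the data.table package, version 1.17.8. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

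The 33 gene lists (704 listed genes, 683 distinct), the comparisons, the named-gene rule and most alternatives were fixed before the data were examined. The pathway lists were cartilage matrix and chondrocyte identity, hypertrophy and mineralising cartilage, matrix proteases and inhibitors, fibrous matrix and remodelling, AP-1 family, immediate early and dissection stress without AP-1, glycolysis and lactate, pyruvate entry into mitochondria, TCA cycle, nuclear-encoded respiratory chain, mitochondrially encoded genes, hypoxia response, amino acid and ATF4 response, fatty acid oxidation, inflammatory cytokines and NF-kB targets, interferon response, TGF-beta and BMP signalling, Wnt signalling and cell cycle. The marker lists were skeletal muscle, erythroid, granulocyte, B cell, T and NK cell, macrophage, osteoclast, osteoblast and osteocyte, endothelial, adipocyte, synovial and connective tissue fibroblast, smooth muscle and pericyte, Schwann cell and nerve, and tendon and ligament. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Between DMM and contralateral c-FosWT libraries 18 passed, between the DMM groups 20 (7 higher, 13 lower), and 0 of them held with an estimated correlation (lowest adjusted p 0.433 and 0.436); fry called 0 and 15. The marrow score is the mean log2 CPM of the erythroid and granulocyte lists, of whose 35 tested genes 1 is in another list (Car2, an osteoclast marker).

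Named genes were, for each main comparison, 15 fixed genes, the 8 largest called changes each way without overlap between groups, with a mean of at least 1 log2 CPM and a symbol that is not a predicted or clone-based name, up to 4 called genes by smallest p of each list that passed, and up to 2 of each other pathway list; with fewer than 5 called genes, the 10 with the smallest p were named as not passing. The secondary comparison had the fixed genes and the 4 largest changes each way under the same exceptions. Some genes that this rule selects are not reported here.

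Scores and ratios were compared with exact permutation tests, 27 in 1 family, and the correlation of the first principal component with the marrow score by a permutation test. The fit was tested on simulated data with 200 of the genes changed. For DMM against contralateral c-FosWT libraries, 31.0% of 2-fold and 75.0% of 4-fold changes were recovered, with 3 false among 109 calls over 17869 genes. For the DMM groups these were 42.0%, 77.0%, and 9 false among 128 calls over 17873 genes, and for the secondary comparison 37.0%, 84.0%, and 4 false among 125 calls over 17859 genes. A list shifted 1.5-fold was recovered in each comparison (adjusted p = 6.16e-16, 2.18e-18 and 7.13e-15), with 0, 3 and 1 of the unchanged lists also called. The simulated libraries did not share an axis of cell composition.

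Numbers in the titles name animals, so 3 contralateral and 3 DMM libraries of c-FosWT mice are pairs from the same animals. Deviations of the pairs from their group means correlated at -0.17, -0.18 and 0.25 across genes, and the consensus correlation of limma within animals was 0.001. The alternatives were other scalings (RLE, upper quartile, library totals, TMM without mitochondrial, muscle, erythroid and granulocyte genes), other filters, DESeq2, limma-voom, robust = FALSE, only the compared groups, a size threshold, muscle or marrow scores as covariates, the animal as a fixed or random block, and each library left out. A cartilage score as a covariate, the omission of 3 pairs of libraries and the sign-flip test of scores within animals were chosen after seeing the data. The contralateral library without a DMM partner stayed in the fit. Exon-level counts were not used here.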

Results

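Articular cartilage of mouse knees was profiled by bulk sequencing of poly(A) RNA 4 weeks after destabilization of the medial meniscus (DMM), an operation that loosens a meniscus and is used as a model of osteoarthritis. The animals were 14 weeks old and of the C57BL/6 strain. Mice with the wild-type label c-FosWT gave 4 libraries from the contralateral knee and 3 from the DMM knee, and mice labelled c-FosDCh, read here as a deletion of Fos in chondrocytes, gave 4 libraries from the DMM knee. Each c-FosWT DMM library came from an animal that also gave a contralateral library. No contralateral c-FosDCh library was analysed here, so the effect of surgery in that genotype, and its difference from wild type, were not tested. Counts assigned to genes were 15190295, 13593454, 16387548 and 17794449 in contralateral replicates 1 to 4, 16400932, 15584177 and 18280558 in c-FosWT DMM replicates 1 to 3, and 13762898, 17887411, 17036730 and 15391211 in c-FosDCh DMM replicates 1 to 4. Levels are given as CPM, counts scaled to the TMM-scaled library total. Genes below 1 CPM rest on few counts, while Fos had 162 to 471 counts in each library.

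The libraries differed in how much marrow and muscle RNA they held beside cartilage RNA. The marrow score, the mean log2 CPM of erythroid and granulocyte genes, was 6.54 ± 0.79 (SD, n = 4) in contralateral, 7.80 ± 0.37 (n = 3) in c-FosWT DMM and 5.66 ± 1.73 (n = 4) in libraries labelled c-FosDCh. In an exact two-sided permutation test it differed by 1.26 between the c-FosWT groups (p = 0.086, adjusted p = 0.27 over 27 such tests) and by -2.14 between the DMM groups (exact p = 0.086, adjusted p = 0.27). The beta-globin gene Hbb-bs had 1930 ± 1060, 5150 ± 1240 and 1270 ± 951 CPM in these groups, and the neutrophil gene S100a8 had 1030 ± 672, 1500 ± 263 and 744 ± 670 CPM. The cartilage score was 8.02 ± 0.19, 7.07 ± 0.78 and 8.07 ± 0.58, with an exact permutation p = 0.057 between the c-FosWT groups and p = 0.17 between the DMM groups (adjusted p = 0.26 and 0.38). Col1a1, a gene of the fibrous matrix and osteoblast lists, had 26300 ± 4620, 32700 ± 1400 and 25900 ± 18700 CPM. Col2a1, the main cartilage collagen gene, had less, at 7760 ± 3310, 4980 ± 2300 and 8450 ± 3230 CPM. Log2 Col1a1 minus log2 Col2a1 was 1.84 ± 0.85, 2.85 ± 0.86 and 1.46 ± 1.43. Exact permutation p was 0.23 between the c-FosWT groups and 0.2 between the DMM groups (adjusted p = 0.41 and 0.39). These tests take the knees as independent. Within the 3 pairs of knees from the same animals, DMM minus contralateral was 0.80, 1.83 and 0.60 for the marrow score and -0.44, -1.54 and -0.86 for the cartilage score. Each gave p = 0.25 in an exact sign-flip test chosen after seeing the data, the smallest that 3 pairs allow. Muscle genes were highest in c-FosWT DMM replicate 1 (score 8.03) and contralateral replicate 2 (score 7.47), with group means of 4.15 ± 2.44, 5.14 ± 2.6 and 3.74 ± 1.59. The first principal component held 58.0% of the variance and correlated with the marrow score over the 11 libraries (Pearson r = -0.97, permutation p = 1e-05, the smallest that the permutations can give; Spearman rho = -0.96, permutation p = 2e-05). The correlation was -0.93 without the 2 libraries farthest from the median score and -0.96 for deviations from the group means.

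**Figure D1:**
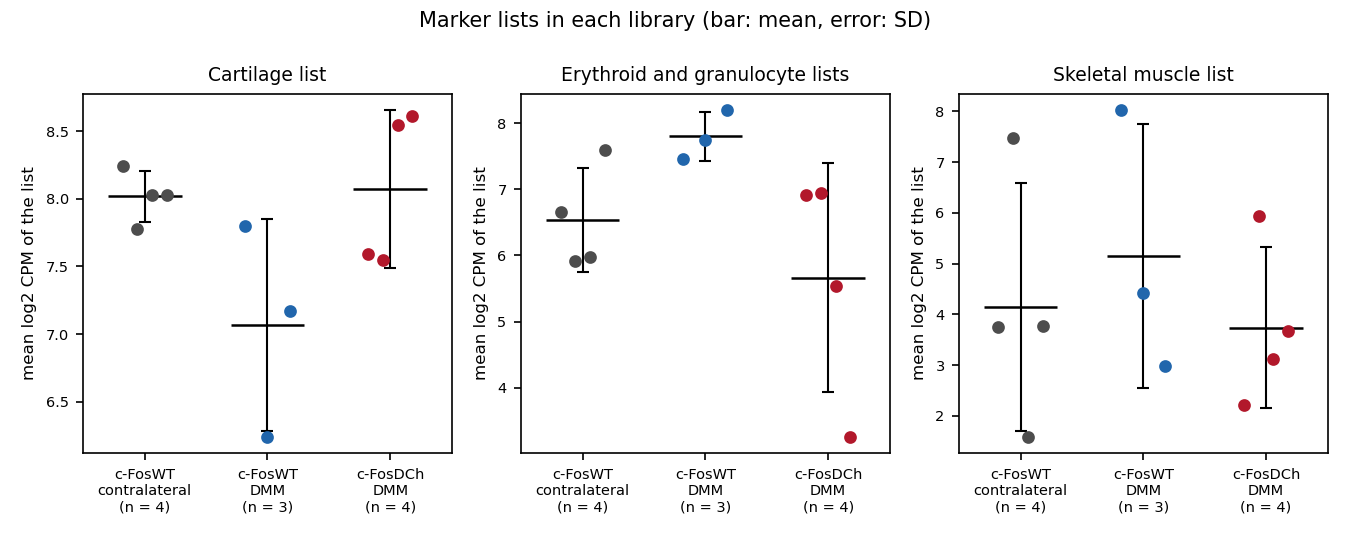
Mean log2 CPM of the cartilage list, the marrow lists (erythroid and granulocyte genes) and the skeletal muscle list in each library, by group, with the group mean (bar) and SD (error bar). The marrow score of the c-FosDCh DMM libraries ranged from 3.26 to 6.94, below the lowest c-FosWT DMM value of 7.46.

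Fos, the targeted gene (ENSMUSG00000021250.13, chromosome 12, 85473890 to 85477273 on the forward strand, GRCm38), encodes a subunit of the AP-1 transcription factor. Its level was 17.1, 24.8, 22.0 and 15.7 CPM in contralateral libraries, 12.1, 14.1 and 9.01 CPM in c-FosWT DMM libraries, and 19.4, 10.9, 29.5 and 33 CPM in the libraries labelled c-FosDCh. The group means were 19.9 ± 4.26 (SD, n = 4), 11.7 ± 2.58 (n = 3) and 23.2 ± 10 CPM (n = 4). Fos was thus not lower in the libraries labelled c-FosDCh than in c-FosWT DMM libraries: the log2 fold change was 0.98 ± 0.35 (SE), with an edgeR adjusted p of 0.0736. The call depended on the tool and on c-FosDCh DMM replicate 2: DESeq2 gave 0.96 with an adjusted p of 0.0341. In turn edgeR without that library gave 1.22 with an adjusted p of 0.0177. The edgeR value was 0.21 (adjusted p = 0.82) with the marrow score as a covariate. With settings chosen after seeing the data, it was 0.64 (0.635) with the cartilage score as a covariate and 0.35 (0.525) without c-FosDCh DMM replicates 3 and 4. The counts cover the whole gene and the deleted part is not given in the labels, so they do not check the genotype, and every direction given for this genotype rests on the label.

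The first comparison, c-FosWT DMM (n = 3) against c-FosWT contralateral libraries (n = 4), addressed the effect of surgery in wild-type cartilage. As a list, cartilage matrix and chondrocyte identity genes were lower after DMM, with a median log2 fold change of -1.0 and negative values in 27 of 30 genes (camera adjusted p = 1.72e-08). The list had adjusted p = 0.479 with an estimated correlation. Within it, Acan, the core protein of aggrecan, had 1220 ± 671 CPM after DMM and 2890 ± 582 CPM in contralateral libraries (log2 fold change -1.25 ± 0.50), and Prg4, which encodes the joint lubricant lubricin, had 2000 ± 937 and 7790 ± 3260 CPM (-1.96 ± 0.71). The edgeR adjusted p was 0.217 for Acan and 0.194 for Prg4, and no cartilage gene passed when adjusted over the list alone. The hypoxia response list was also lower (median -0.91, 18 of 23 genes negative, camera adjusted p = 1.71e-06). This list had adjusted p = 0.433 with an estimated correlation, and 14 of its genes were lower when adjusted over the list alone. So were TGF-beta and BMP signalling (median -0.64, 28 of 28 genes negative, camera adjusted p = 4.28e-07) and Wnt signalling (median -0.57, 21 of 26, camera adjusted p = 0.00084). Both had adjusted p = 0.433 with an estimated correlation. Adjusted over the list alone, 3 TGF-beta and BMP genes and 0 Wnt genes were lower. In the same libraries the marrow score was 7.80 ± 0.37, against 6.54 ± 0.79 in contralateral libraries, and the erythroid list had a median of 1.56.

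Genes of fibrous matrix fell as a list (median -0.49, camera adjusted p = 0.00084), as did genes of hypertrophy and mineralising cartilage (median -0.47, camera adjusted p = 0.000948). They had adjusted p = 0.558 and adjusted p = 0.433 with an estimated correlation. The immediate early and dissection stress list fell too (median -0.46, camera adjusted p = 0.00824), with adjusted p = 0.433 with an estimated correlation. Adjusted over the list alone, 6 of its genes were lower and 1 was higher, against 1 lower fibrous gene and 0 hypertrophy genes. Among marker lists of other cells, osteoblast and osteocyte (median -0.41, camera adjusted p = 0.0089), Schwann cell and nerve (median -0.99, 0.0113) and tendon and ligament genes (median -0.64, 0.0197) were lower. Their adjusted p values were 0.714, 0.433 and 0.433 with an estimated correlation, and 0, 1 and 2 genes were lower when adjusted over the list alone. The marrow score of these groups was 7.80 ± 0.37 after DMM and 6.54 ± 0.79 in contralateral libraries.

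Erythroid genes were higher after DMM as a list (median 1.56, 16 of 16 genes positive, camera adjusted p = 1.01e-10), and so were cell cycle genes (median 1.12, 29 of 29, camera adjusted p = 1.99e-11). With an estimated correlation, the erythroid list had adjusted p = 0.433 and the cell cycle list adjusted p = 0.51. Granulocyte (median 0.74, camera adjusted p = 0.00751), T and NK cell (median 0.73, 0.0089), interferon response (median 0.52, 0.000174) and skeletal muscle genes (median 0.99, 0.0422) were higher as lists. In that order they had adjusted p = 0.765, 0.715, 0.715 and 0.863 with an estimated correlation. Genes of the nuclear-encoded respiratory chain (median 0.15, camera adjusted p = 0.00171) and of the TCA cycle (median 0.20, 0.00883) were higher by little, with adjusted p = 0.715 and 0.714 with an estimated correlation. No gene of these 8 lists passed when adjusted over the list alone. With the animal as a fixed block over the 3 pairs, the TCA cycle and skeletal muscle lists no longer passed (camera adjusted p = 0.0801 and 0.936), while osteoclast genes passed as higher (0.00278 against 0.0805 without the block) and fibroblast genes as lower (0.0143 against 0.06). In the fit without the block, the osteoclast and fibroblast lists had adjusted p = 0.765 and 0.715 with an estimated correlation. In the same libraries the marrow score was 7.80 ± 0.37, against 6.54 ± 0.79 in contralateral libraries. The other 15 lists did not pass (camera adjusted p 0.06 to 0.994), and they gave 1 gene, a lower smooth muscle and pericyte gene, when adjusted over the list alone. Median, mean and test differed in sign for matrix proteases (0.01, -0.09, down), inflammatory genes (0.11, -0.02, up), mitochondrially encoded genes (0.08, 0.05, down) and amino acid and ATF4 genes (-0.05, 0.01, up). Upper quartile scaling turned the medians of matrix proteases and of pyruvate entry into mitochondria from 0.01 to -0.04 and from 0.03 to -0.02.

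Gene by gene, 0 of 18125 genes passed the edgeR test between these groups, with 3605 at an unadjusted p under 0.05 and a lowest adjusted p of 0.182. On the same counts limma-voom called 0, whereas DESeq2 called 902 (370 higher, 532 lower). DESeq2 calls included 8 lower cartilage genes, 5 lower hypoxia genes and 4 lower genes each of the TGF-beta and BMP and the Wnt lists. The 10 genes with the smallest edgeR p, named although none passed, included Ube2o, a ubiquitin-conjugating enzyme of maturing red cells (231 ± 54.6 CPM after DMM, 87.9 ± 23.4 CPM contralateral; log2 fold change 1.40 ± 0.23). Another was Cyp26b1, which degrades retinoic acid (18.9 ± 5.29 and 47.4 ± 12.2 CPM; -1.33 ± 0.24). Bsdc1 (0.88 ± 0.15), Narf (0.68 ± 0.12), the deubiquitinase gene Otud5 (0.63 ± 0.12), the cullin gene Cul4a (0.49 ± 0.10) and the histidyl-tRNA synthetase gene Hars (0.55 ± 0.11) also had positive values. The amino acid transporter gene Slc7a2 (-1.06 ± 0.21) and the enolase gene Eno2 (-0.92 ± 0.18) had negative values. Each of these genes had values beyond those of every contralateral library in 3 of 3 DMM libraries. As they were picked by small p, this follows in part from the choice, and Fosl2 had it too (edgeR adjusted p = 0.606). Fosb, a Fos relative, had a value of -1.21 ± 0.37 (adjusted p = 0.182) and Fos one of -0.76 ± 0.35 (0.254). Junb (-0.56 ± 0.23), Jun (-0.37 ± 0.26), Fosl1 (-0.89 ± 0.63) and Fosl2 (0.14 ± 0.16) did not pass either. Col10a1, the collagen of hypertrophic chondrocytes (-1.22 ± 0.61), Col2a1, the main cartilage collagen (-0.64 ± 0.47), the metalloprotease genes Mmp13 (0.40 ± 0.44), Mmp3 (-0.90 ± 0.59) and Adamts5 (-0.34 ± 0.25), and the metabolic genes Pdk1 (-0.60 ± 0.33) and Ldha (-0.36 ± 0.28) were within the spread allowed by the test. With a cartilage score as a covariate, a setting chosen after seeing the data, Col2a1, Pdk1 and Ldha turned to 0.33, 0.03 and 0.20. Col2a1 is itself a member of the list behind that score, so its turn is in part built in. Without the 2 muscle-rich libraries, also chosen after seeing the data, Mmp13 turned to -0.03. DESeq2 passed the genes named for their small p and Fosb (adjusted p = 0.0422) and Prg4 (0.0419).

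**Figure D2:**
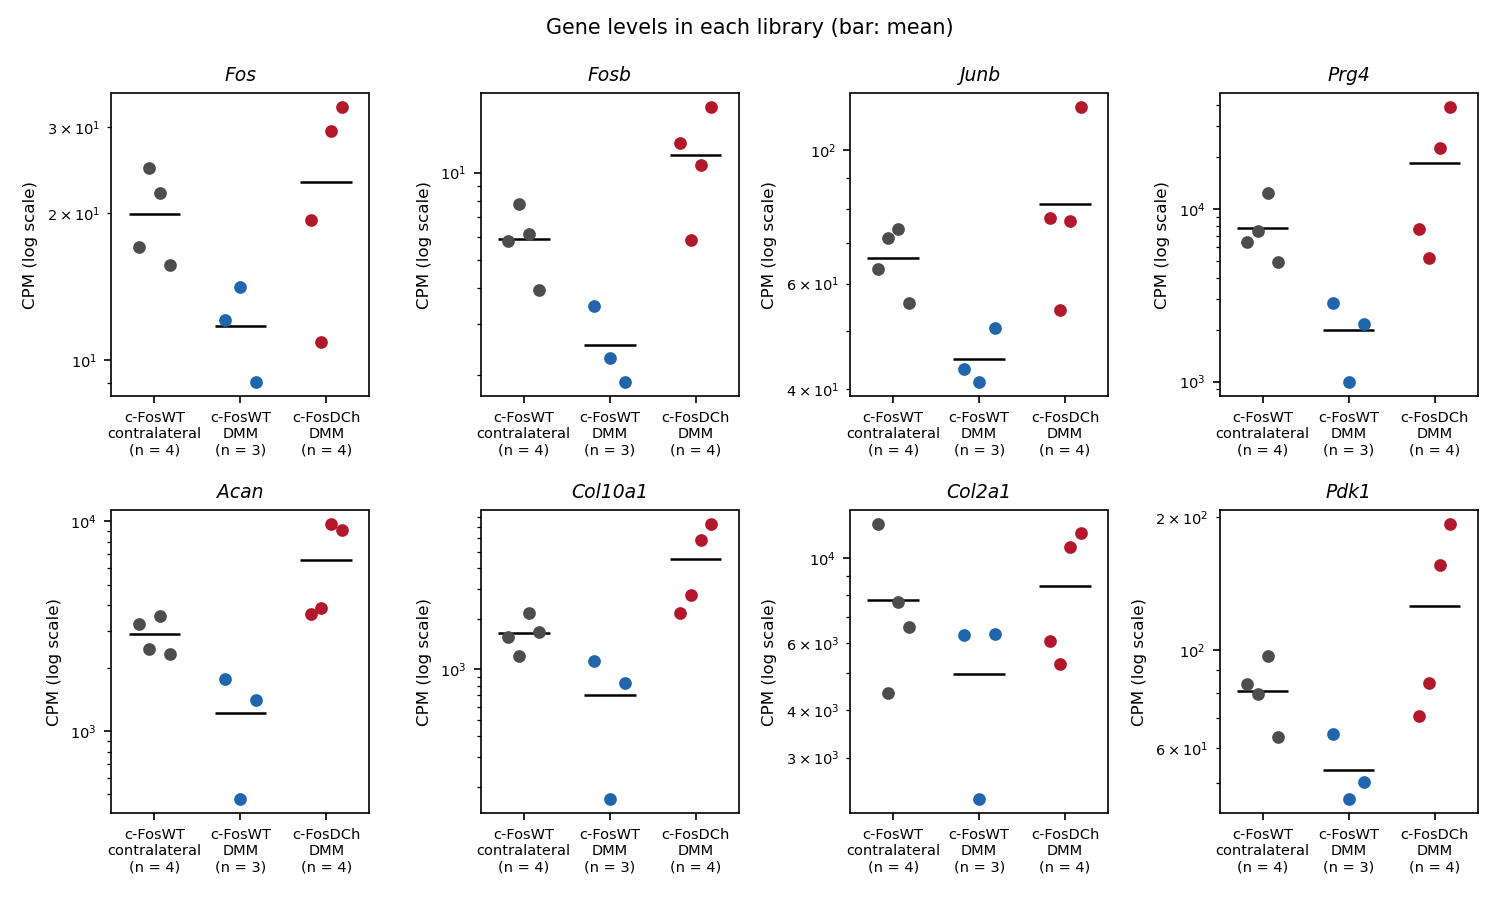
CPM on a log axis of named genes in each library of the 3 groups, with the group mean as a bar. Fos lies between 10.9 and 33 CPM in the libraries labelled c-FosDCh and between 9.01 and 14.1 CPM in c-FosWT DMM libraries.

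The second comparison set the libraries labelled c-FosDCh (n = 4) against c-FosWT libraries (n = 3), both from DMM knees, and addressed how operated joints with this label differ from wild type. Of 30 cartilage list genes 15 were higher in the libraries labelled c-FosDCh and 5 had negative values, and the list had adjusted p = 0.436 with an estimated correlation. Among the higher genes, Sox9, the master transcription factor of chondrocytes, had 275 ± 130 CPM against 50.6 ± 27.5 CPM (SD), a log2 fold change of 2.44 ± 0.48 (SE). Acan (chromosome 7, 79053483 to 79115099) had 6570 ± 3260 against 1220 ± 671 CPM (2.43 ± 0.53) and Prg4 (chromosome 1, 150449412 to 150466165) had 18500 ± 15500 against 2000 ± 937 CPM (3.21 ± 0.76). Fosb (chromosome 7, 19302696 to 19310051) was higher as well, at 11.4 ± 4.52 against 2.55 ± 0.813 CPM (2.16 ± 0.38). Of 16 erythroid genes 7 were lower, among them Alas2, the enzyme that starts haem synthesis, at 79.6 ± 54.3 against 367 ± 73.3 CPM (-2.20 ± 0.55). The erythroid list had adjusted p = 0.436 with an estimated correlation. The edgeR adjusted p was 0.0332 for Sox9, Acan and Fosb, 0.0336 for Prg4 and 0.0364 for Alas2. Each was beyond every c-FosWT DMM library in 4 of 4 libraries, which for Sox9 and Alas2 follows in part from choosing them by small p. In all, 2616 of 18125 genes passed (1929 higher, 687 lower, 73.7% higher; lowest adjusted p 0.0332), with 7074 at an unadjusted p under 0.05. Scaling by library totals alone called 2157, of which 54.5% were higher, and moved the median fold change of all genes by -0.17 in this comparison and by -0.16 between the libraries labelled c-FosDCh and contralateral libraries.

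These calls depended on which libraries and covariates entered the fit. Without c-FosWT DMM replicate 2 or 3, c-FosDCh DMM replicate 3 or 4, or contralateral replicate 1, which is in neither group, 0 genes passed. The count was 1 without contralateral replicate 2, 1355 without contralateral replicate 3, 4449 without c-FosDCh DMM replicate 1 and 4626 without c-FosDCh DMM replicate 2. A fit of these 2 groups alone, and fits with a muscle score, a marrow score or (chosen after seeing the data) a cartilage score as a covariate, also left 0 genes. Their lowest adjusted p values were 0.0846, 0.0571, 0.335 and 0.402. Without single libraries of the DMM groups, log2 fold changes ranged from 2.06 to 2.83 for Sox9, 2.03 to 2.76 for Acan, 1.92 to 2.41 for Fosb and 2.57 to 3.52 for Prg4. With the muscle score as a covariate Sox9, Acan and Fosb were at 2.46, 2.42 and 2.26, with the marrow score at 1.67, 1.64 and 1.5, and with the cartilage score at 1.31, 1.21 and 1.76. Sox9 and Acan are members of the list behind the cartilage score, so their smaller values with it are in part built in.

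In the cartilage list 15 of 30 genes were higher and 0 lower (18 and 2 when adjusted over the list alone), with a median log2 fold change of 1.58 (camera adjusted p = 5.34e-07). It had adjusted p = 0.436 with an estimated correlation. The cartilage score was 7.59, 7.55, 8.55 and 8.61 in c-FosDCh DMM replicates 1 to 4 and 7.80, 6.24 and 7.17 in c-FosWT DMM replicates 1 to 3. Without c-FosDCh DMM replicates 3 and 4, an omission chosen after seeing the data, the list's median was 0.97 (camera adjusted p = 2.67e-06; adjusted p = 0.439 with an estimated correlation). No list passed with an estimated correlation in that fit (lowest adjusted p = 0.393). Beside Sox9 and Acan, Col27a1, a fibrillar cartilage collagen gene (1110 ± 396 against 371 ± 130 CPM; 1.58 ± 0.36), and Wwp2, a ubiquitin ligase gene (1050 ± 391 against 338 ± 87.1 CPM; 1.63 ± 0.35), rose. The value of Col2a1 was within the spread (0.76 ± 0.47, adjusted p = 0.239). In the hypertrophy list 5 of 17 genes were higher and 0 lower (7 and 1 adjusted over the list alone; median 0.76, camera adjusted p = 0.00931). The hypertrophy list had adjusted p = 0.436 with an estimated correlation. Its called genes included Col10a1 (chromosome 10, 34389981 to 34397085) at 4510 ± 2460 against 711 ± 494 CPM (2.67 ± 0.65), the pyrophosphate-generating enzyme gene Enpp1 (1.97 ± 0.37), the pyrophosphate transporter gene Ank (1.45 ± 0.28) and the angiogenic factor gene Vegfa (1.45 ± 0.31). Fibrous matrix genes rose in 8 of 28 cases with 0 lower (11 and 0 adjusted over the list alone; median 0.62, camera adjusted p = 0.000505). Fibrous matrix had adjusted p = 0.436 with an estimated correlation. The called genes included the fibronectin gene Fn1 (1.74 ± 0.38), the decorin gene Dcn (2.17 ± 0.48) and the collagen cross-linking oxidase gene Lox (1.69 ± 0.40). TGF-beta and BMP genes rose in 11 of 28 cases with 0 lower (20 and 0 adjusted over the list alone; median 1.00, camera adjusted p = 1.48e-07). TGF-beta and BMP signalling had adjusted p = 0.436 with an estimated correlation. Its median was 0.57 without c-FosDCh DMM replicates 3 and 4 (camera adjusted p = 2e-11; adjusted p = 0.393 with an estimated correlation). Its members past the test included the TGF-beta-binding protein gene Ltbp3 (1.44 ± 0.28), the BMP target Id1 (1.29 ± 0.26), the BMP antagonist gene Chrd (1.01 ± 0.21) and the ligand gene Tgfb3 (0.75 ± 0.17). In the same libraries the cartilage score was 8.07 ± 0.58 against 7.07 ± 0.78, and the marrow score 5.66 ± 1.73 against 7.80 ± 0.37.

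Of the AP-1 family, Fosb and Junb (0.86 ± 0.23, adjusted p = 0.0392) rose, 2 of 12 genes, with 5 higher and 0 lower when adjusted over the list alone. The AP-1 list had a median of 0.72 and did not pass (camera adjusted p = 0.109). Jun (0.76 ± 0.26, adjusted p = 0.0667), Fosl1 (1.47 ± 0.62, 0.109) and Fosl2 (0.15 ± 0.16, 0.476) did not pass, and DESeq2 passed Jun (adjusted p = 0.0329). Fosl2 turned to -0.05 when scaled by library totals, to -0.15 with the marrow score as a covariate and to -0.03 without c-FosDCh DMM replicate 4. Among the other immediate early and dissection stress genes 12 of 27 were higher and 1 lower (13 and 3 adjusted over the list alone; median 0.67, camera adjusted p = 0.00708). Immediate early genes had adjusted p = 0.436 with an estimated correlation. They included the small Maf factor gene Maff (29.4 ± 20.1 against 5.46 ± 2.0 CPM; 2.42 ± 0.51), the activity-regulated gene Arc (1.55 ± 0.28), Ier3 (1.36 ± 0.26) and Socs3, an inhibitor of cytokine signalling (0.59 ± 0.12). The lower gene was Btg2, an antiproliferative gene (-0.73 ± 0.20), named after its value was seen. The marrow score of these libraries was 5.66 ± 1.73 against 7.80 ± 0.37.

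The hypoxia response list rose in 17 of 23 genes with 0 lower (18 and 0 adjusted over the list alone; median 1.52, camera adjusted p = 1.93e-08). Hypoxia genes had adjusted p = 0.436 with an estimated correlation. Their mean log2 CPM was 6.05 and 6.40 in c-FosDCh DMM replicates 3 and 4, against 5.50 and 5.45 in replicates 1 and 2, and without replicates 3 and 4 the median was 0.96 (camera adjusted p = 2e-11; adjusted p = 0.393 with an estimated correlation). Called hypoxia genes included Ak4, a mitochondrial adenylate kinase gene (91.8 ± 56.6 against 14.5 ± 6.60 CPM; 2.66 ± 0.54), the stanniocalcin gene Stc2 (2.24 ± 0.46), the mTOR inhibitor gene Ddit4 (1.53 ± 0.31) and the transcriptional repressor gene Bhlhe40 (1.08 ± 0.20). Glycolysis genes were higher in 5 of 21 cases and lower in 1 (11 and 1 adjusted over the list alone; median 0.60, camera adjusted p = 0.0164). Glycolysis had adjusted p = 0.436 with an estimated correlation. Its mean was 6.77 and 7.01 in replicates 3 and 4, against 6.53 and 6.45 in replicates 1 and 2, and without replicates 3 and 4 the median was 0.26 (camera adjusted p = 0.027; adjusted p = 0.447 with an estimated correlation). In this list the glucose transporter gene Slc2a1 (194 ± 137 against 35.8 ± 12.1 CPM; 2.44 ± 0.53), the enolase gene Eno1 (1.05 ± 0.25) and the phosphofructokinase genes Pfkl (1.59 ± 0.39) and Pfkp (1.59 ± 0.43) rose. The lactate transporter gene Slc16a1, named after its value was seen, fell (-1.55 ± 0.45). Ldha, the lactate dehydrogenase subunit gene, had 480 ± 159 against 281 ± 84.4 CPM (0.77 ± 0.28, edgeR adjusted p = 0.0792; DESeq2 adjusted p = 0.0399). Pdk1 (chromosome 2, 71873224 to 71903858), a pyruvate dehydrogenase kinase gene, rose from 53.5 ± 9.69 to 126 ± 58.4 CPM (1.24 ± 0.33, adjusted p = 0.0401). It was the single called gene of 14 in the list of pyruvate entry, which did not pass (median -0.12, camera adjusted p = 0.474; 0 genes adjusted over the list alone). TCA cycle genes fell in 6 of 18 cases (9 adjusted over the list alone; median -0.35, camera adjusted p = 0.000643). The TCA cycle list had adjusted p = 0.436 with an estimated correlation. Among its lower genes were the citrate synthase gene Cs (-0.66 ± 0.19), Mdh2 (-0.57 ± 0.15), Sdhd (-0.56 ± 0.16) and Dlst (-0.52 ± 0.13). Nuclear genes of the respiratory chain fell in 6 of 46 cases (12 adjusted over the list alone; median -0.32, camera adjusted p = 2.19e-05). That list, too, had adjusted p = 0.436 with an estimated correlation, and its median was -0.20 without replicates 3 and 4 (camera adjusted p = 0.000603; adjusted p = 0.447 with an estimated correlation). Its lower genes included the ATP synthase genes Atp5b (-0.67 ± 0.14) and Atp5a1 (-0.50 ± 0.11) and the complex I gene Ndufa10 (-0.54 ± 0.10). The marrow score differed in the same libraries, 5.66 ± 1.73 against 7.80 ± 0.37.

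Erythroid genes fell in 7 of 16 cases (16 adjusted over the list alone; median -2.19, camera adjusted p = 2.23e-09). Erythroid genes had adjusted p = 0.436 with an estimated correlation. With Alas2 they included Epb42, a red cell membrane protein gene (-2.37 ± 0.67), the transferrin receptor gene Tfrc (-1.46 ± 0.42) and the carbonic anhydrase gene Car2 (-2.27 ± 0.66). Cell cycle genes (median -1.56, 29 of 29 negative; camera adjusted p = 1.86e-10) held 0 called genes and 25 lower genes adjusted over the list alone. This list had adjusted p = 0.436 with an estimated correlation. Interferon response genes fell in 5 of 25 cases (16 adjusted over the list alone; median -1.12, camera adjusted p = 1.32e-08). Interferon response had adjusted p = 0.436 with an estimated correlation. Lower genes included the antiviral genes Rsad2 (-2.17 ± 0.55) and Isg15 (-1.95 ± 0.52) and the interferon regulatory factor genes Irf7 (-1.49 ± 0.39) and Irf9 (-0.90 ± 0.22). Osteoclast genes fell in 5 of 14 cases and rose in 1 (11 and 1 adjusted over the list alone; median -1.08, camera adjusted p = 7.64e-05). Osteoclast genes had adjusted p = 0.436 with an estimated correlation and included Acp5, the tartrate-resistant phosphatase gene (-1.13 ± 0.32), Oscar (-1.11 ± 0.29), and the fusion genes Ocstamp (-1.33 ± 0.37) and Dcstamp (-1.05 ± 0.30). The higher gene was Nfatc1, a transcription factor gene (0.42 ± 0.12), named after its value was seen. Endothelial genes were lower as a list (median -0.99, camera adjusted p = 7.64e-05). They had adjusted p = 0.436 with an estimated correlation, with Robo4 lower (-1.11 ± 0.31), the transcription factor gene Erg higher (1.33 ± 0.26), and 14 lower and 1 higher adjusted over the list alone. Macrophage genes were lower as a list (median -1.04, camera adjusted p = 0.000261), with adjusted p = 0.436 with an estimated correlation. Their 1 called gene, the lipopolysaccharide co-receptor gene Cd14, rose (2.46 ± 0.54; 1 adjusted over the list alone). T and NK cell genes were lower (median -1.41, camera adjusted p = 4.87e-05), with adjusted p = 0.436 with an estimated correlation. The granzyme gene Gzma was the single called gene (-1.79 ± 0.50; 0 adjusted over the list alone). Its value ranged from -2.59 to -1.53 without single libraries of the DMM groups, and its call was lost in 6 of 7 such fits. B cell (median -1.51, camera adjusted p = 5.35e-05), granulocyte (median -1.08, 0.000505), adipocyte (median -1.20, 0.000202) and skeletal muscle genes (median -2.55, 0.0296) were lower as lists. They had adjusted p = 0.436, 0.538, 0.436 and 0.744 with an estimated correlation. These 4 lists held 0 called genes by edgeR, over all genes or adjusted over the list alone. DESeq2 called 2, 0, 4 and 1 of their genes lower. The mean log2 CPM of c-FosDCh DMM replicates 3 and 4 lay far below that of replicates 1 and 2 for granulocyte (5.67 and 2.73 against 7.54 and 6.93), adipocyte (1.49 and 0.24 against 3.75 and 3.78) and macrophage genes (4.09 and 3.04 against 5.45 and 5.14). They were also lower for interferon (2.13 and 1.19 against 3.48 and 2.89) and endothelial genes (3.97 and 3.24 against 4.92 and 5.03). Without replicates 3 and 4 the granulocyte, adipocyte and macrophage medians were -0.30, -0.38 and -0.46. The median was then -1.58 for erythroid, -0.79 for B cell, -0.71 for T and NK cell, -0.57 for interferon, -0.88 for cell cycle, -0.65 for osteoclast and -0.45 for endothelial genes. These lists still passed except the granulocyte list, with adjusted p from 0.393 to 0.447 with an estimated correlation. The granulocyte and skeletal muscle lists no longer passed (camera adjusted p = 0.0919 and 0.125). The marrow score was 5.66 ± 1.73 against 7.80 ± 0.37 and the muscle score 3.74 ± 1.59 against 5.14 ± 2.6.

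Several lists that did not pass also held called genes. Over all tested genes 14.4% were called, so a few called genes in a list are no result about that list. Wnt signalling (median 0.34, camera adjusted p = 0.0925) had 5 of 26 genes higher and 0 lower (9 and 0 adjusted over the list alone), including the secreted Wnt modulator gene Dkk3 (0.98 ± 0.20) and the receptor gene Fzd9 (2.27 ± 0.52). Matrix proteases and inhibitors (median -0.33, camera adjusted p = 0.649) had 4 of 24 higher (4 adjusted over the list alone), including the serine protease gene Htra1 (1.57 ± 0.25) and the protease inhibitor gene Timp3 (2.15 ± 0.49). In that list Mmp3 (0.81 ± 0.59), Mmp13 (-0.58 ± 0.44) and Adamts5 (0.03 ± 0.25) did not pass. Adamts5 was -0.17 when scaled by library totals, -0.44 and -0.03 with the marrow and the cartilage score as covariates, -0.11 without c-FosWT DMM replicate 3 and -0.09 without c-FosDCh DMM replicate 4. Inflammatory genes (median -0.54, camera adjusted p = 0.649) had 5 of 24 higher and 2 lower (6 and 2 adjusted over the list alone), among them the prostaglandin synthase gene Ptges (0.95 ± 0.18) and the hyaluronan-binding gene Tnfaip6 (1.85 ± 0.48). Amino acid and ATF4 response genes (median 0.21, camera adjusted p = 0.795) had Nupr1 (1.5 ± 0.31) and the glutamine transporter gene Slc38a2 (0.96 ± 0.25) higher, 2 of 26 (2 adjusted over the list alone). Fatty acid oxidation genes (median -0.22, camera adjusted p = 0.0798) had Cpt1a, which imports fatty acids into mitochondria (-0.93 ± 0.24), and Acadl (-0.76 ± 0.22) lower, 2 of 20 (0 adjusted over the list alone). Of 7 mitochondrially encoded genes 0 passed by edgeR, over all genes or adjusted over the list alone (median -0.86, camera adjusted p = 0.112), and DESeq2 called 2 lower. The fit gave medians of 0.07 for osteoblast and osteocyte, 0.04 for synovial and connective tissue fibroblast and 0.05 for Schwann cell and nerve genes, which library totals turned to -0.08, -0.11 and -0.12. Their camera adjusted p values were 0.805, 0.973 and 0.589, and the mean of the fibroblast list was -0.03 with a test pointing up. Smooth muscle and pericyte genes (median -0.31, camera adjusted p = 0.407) and tendon and ligament genes (median 0.78, 0.0551) did not pass. Without c-FosDCh DMM replicates 3 and 4, Wnt (median 0.55, camera adjusted p = 0.000197), tendon (0.92, 0.00917), osteoblast (0.33, 0.0161) and fibroblast genes (0.38, 0.0379) passed as higher, and mitochondrially encoded (-1.17, 0.00917) and fatty acid oxidation genes (-0.18, 0.0431) as lower. These 6 lists had adjusted p from 0.393 to 0.476 with an estimated correlation. Adjusted over the list alone, 4 osteoblast, 0 fibroblast, 1 smooth muscle, 4 Schwann cell and 5 tendon genes were higher, and 1 Schwann cell gene was lower. The marrow score was 5.66 ± 1.73 against 7.80 ± 0.37 in these libraries.

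The largest called differences were in Msmp (269 ± 181 against 14.6 ± 6.74 CPM; 4.20 ± 1.04), Sectm1b (3.71 ± 0.88), Ppp1r3g, a glycogen-targeting phosphatase subunit gene (3.68 ± 0.93), and Etnppl, an ethanolamine-phosphate lyase gene (3.43 ± 0.89). They were followed by the glycine cleavage gene Gldc (3.32 ± 0.71), Cytl1, a secreted protein gene of cartilage (5430 ± 3970 against 550 ± 344 CPM; 3.30 ± 0.81), the sodium channel gene Scn11a (3.26 ± 0.62) and Mgarp (3.24 ± 0.73). Several of these rested on few counts in c-FosWT DMM replicates 1 to 3. Sectm1b had 11, 2 and 10 counts there, Ppp1r3g 14, 0 and 5, and Etnppl 39, 2 and 38. Scn11a had 12, 8 and 10 and Mgarp 15, 4 and 9. Those that fell most were the immunoglobulin light chain genes Igkv19-93 (-3.44 ± 0.92) and Iglc3 (-2.53 ± 0.74), Pklr, the pyruvate kinase gene of liver and red cells (3.65 ± 2.64 against 20.2 ± 5.22 CPM; -2.46 ± 0.66), Epb42, Mylk3 (-2.35 ± 0.63), Apol11a (-2.35 ± 0.70), Apol11b (-2.35 ± 0.62) and Redrum (-2.33 ± 0.69). Immunoglobulin and Apol11 genes have close copies that can share reads, so their counts are uncertain. Igkv19-93 had 7, 4, 1 and 2 counts in c-FosDCh DMM replicates 1 to 4. Without single libraries, values ranged from 3.04 to 4.98 for Ppp1r3g, 2.74 to 4.05 for Sectm1b and 3.7 to 4.54 for Msmp. Those of Igkv19-93 ranged from -4.07 to -2.83 and those of Mylk3 from -3.05 to -2.08, so the order of the largest changes is not stable. The rule that named the genes of this paragraph required a call and no overlap between the groups, so their separation in 4 of 4 libraries follows from the choice, and their edgeR adjusted p ran from 0.0332 to 0.0492. The marrow score was 5.66 ± 1.73 against 7.80 ± 0.37.

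**Figure D3:**
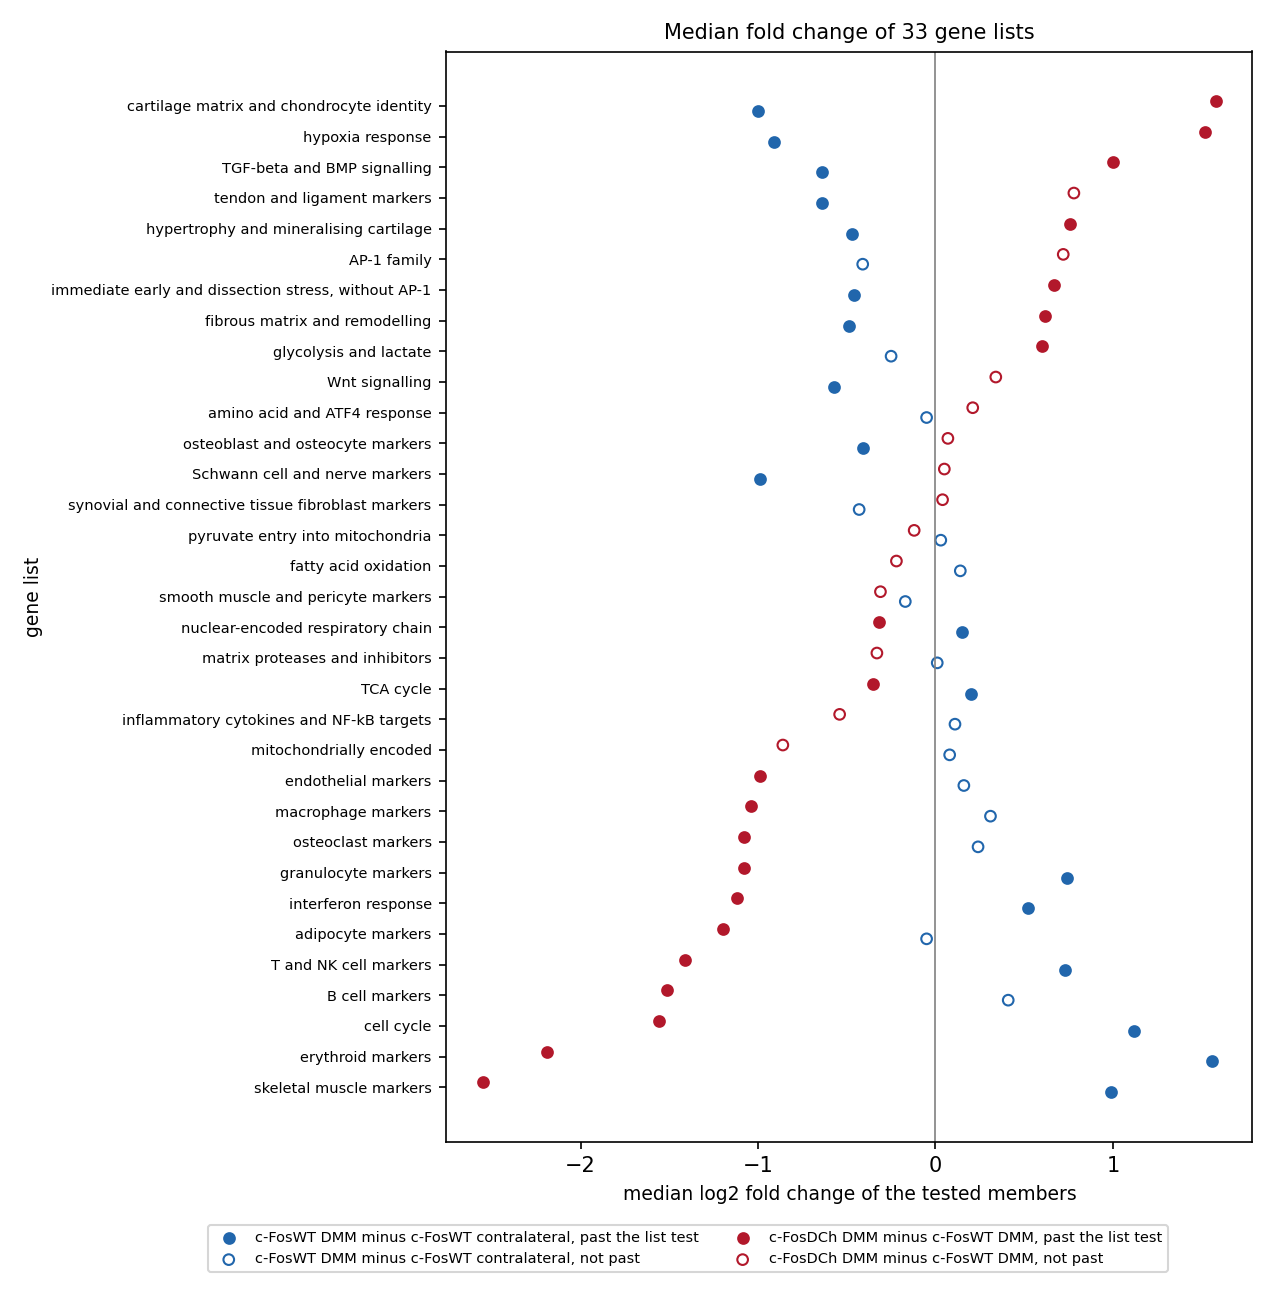
Median log2 fold change of the tested members of 33 gene lists in c-FosWT DMM minus contralateral (blue) and c-FosDCh DMM minus c-FosWT DMM libraries (red), with filled points for lists past the camera test. The cartilage list lies at -1.0 and 1.58, and the erythroid list at 1.56 and -2.19.

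The secondary comparison, libraries labelled c-FosDCh from DMM knees (n = 4) against c-FosWT contralateral libraries (n = 4), joins surgery and genotype. Adipocyte (median log2 fold change -1.10), B cell (-1.03) and endothelial genes (-0.85) were lower as lists (camera adjusted p = 6.04e-12, 6.45e-09 and 6.74e-11), and each had adjusted p = 0.48 with an estimated correlation. Replicates 3 and 4 of the libraries labelled c-FosDCh were far lower in these lists than replicates 1 and 2, with adipocyte means of 1.49 and 0.24 against 3.75 and 3.78 log2 CPM. Without replicates 3 and 4 the medians were -0.31, -0.24 and -0.29 (camera adjusted p = 0.000109, 0.0211 and 4.16e-05). Hypoxia response (0.52, camera adjusted p = 5.71e-06) and glycolysis genes (0.42, 2.44e-05) were higher, each with adjusted p = 0.48 with an estimated correlation. Of 33 lists 23 passed, 5 higher and 18 lower, and 0 passed with an estimated correlation (lowest adjusted p = 0.48) or with fry (lowest adjusted p = 0.29). The other higher lists were the cartilage (0.40), TGF-beta and BMP (0.28) and fibrous matrix lists (0.22), with camera adjusted p = 0.02, 0.00135 and 0.0485. They had adjusted p = 0.655, 0.48 and 0.619 with an estimated correlation. Without c-FosDCh DMM replicates 3 and 4, 10 lists passed, 3 higher and 7 lower. Hypoxia, glycolysis and TGF-beta and BMP genes were then no longer among them (camera adjusted p = 0.738, 0.0925 and 0.328). The cartilage list turned lower (median -0.24, camera adjusted p = 0.00143), and the granulocyte and cell cycle lists turned from lower (-0.38 and -0.42) to higher (0.43 and 0.25, camera adjusted p = 8.14e-05 and 0.000171). Each list had adjusted p = 0.976 with an estimated correlation. Adjusted over the list alone, 1 hypoxia gene was higher and 1 adipocyte and 1 Schwann cell gene were lower. Median, mean and test differed in sign for the hypertrophy list (-0.07, 0.09, up) and the tendon list (0.05, -0.04, up). Library totals turned the tendon median to -0.12 and that of amino acid and ATF4 genes from 0.09 to -0.11. The marrow score was 5.66 ± 1.73 against 6.54 ± 0.79.

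By gene, edgeR called 0 of 18125 genes in that comparison, with 1512 at an unadjusted p under 0.05 and a lowest adjusted p of 0.584. In the same comparison limma-voom called 0 and DESeq2 41 (17 higher, 24 lower). Without contralateral replicate 2, edgeR called 1 gene, which was lower. Among the 10 genes with the smallest p, none past the test, Chil1, which encodes a chitinase-like glycoprotein of cartilage, had 506 ± 239 against 138 ± 52.3 CPM (1.87 ± 0.38). Pck1, the gluconeogenic enzyme gene, had 0.769 ± 0.548 against 6.19 ± 3.6 CPM (-2.97 ± 0.60). Acsbg1 (2.29 ± 0.44), Gm49069 (2.37 ± 0.49) and Abhd8 (0.51 ± 0.11) had positive values, and Klf11 (-0.79 ± 0.15), Rps16 (-0.60 ± 0.12), Zdhhc14 (-1.36 ± 0.28), Htr1b (-1.63 ± 0.34) and Gpr83 (-1.88 ± 0.40) negative ones. DESeq2 passed all but Htr1b and Gpr83. Acan (1.18 ± 0.45), Col10a1 (1.45 ± 0.56), Prg4 (1.25 ± 0.63), Fosb (0.95 ± 0.33), Junb (0.30 ± 0.21), Jun (0.39 ± 0.23), Fosl2 (0.29 ± 0.15), Pdk1 (0.64 ± 0.30), Ldha (0.42 ± 0.26) and Adamts5 (-0.31 ± 0.23) did not pass. Fos (0.22 ± 0.31), Fosl1 (0.58 ± 0.53), Col2a1 (0.12 ± 0.43), Mmp3 (-0.09 ± 0.53) and Mmp13 (-0.18 ± 0.41) lay close to 0 against their errors.

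Both main comparisons use the c-FosWT DMM libraries, with opposite sign. No gene passed in both by edgeR, as the first comparison called 0, also at an adjusted p of 0.1, where the second called 5899. Across the 18125 genes, which are not independent replicates, the differences of mean log2 CPM correlated at -0.86. In 20 simulations of unchanged groups that shared those libraries, the mean correlation was -0.56 and the lowest -0.58. The covariance was -0.441 against a simulated -0.094, a difference of -0.347. The simulated values varied little, whereas the real libraries shared an axis that held 58.0% of the variance. The simulations are therefore no fair measure of chance here. As the 3 shared libraries cannot be split into parts of at least 2, part or all of the difference may come from them.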

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

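No test in this part was chosen only after its result was seen. Of 310 groups of 4 values looked at, 16 held a library whose gap to its nearest neighbour took up most of the group's range. Chance alone gives about 1 in 20, so this count is near that of chance and the flagged values are no result by themselves. Contralateral replicate 4 held 9 of these values, c-FosDCh DMM replicate 4 held 6 and c-FosDCh DMM replicate 3 held 1. These replicates had marrow scores of 7.60, 3.26 and 5.54.

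In contralateral replicate 4, Alas2 was at 7.97 log2 CPM against 6.49 to 6.67 in the other contralateral libraries, Pklr at 3.21 against 1.62 to 1.66, Apol11b at 4.84 against 2.88 to 3.16 and Otud5 at 6.69 against 6.30 to 6.32. Gpr83 was at 1.03 against 0.00 to 0.17, Arc at 2.04 against 3.00 to 3.15 and Fzd9 at 5.15 against 6.24 to 6.32. The endothelial list had a mean of 5.47 log2 CPM in this library against 5.13 to 5.18. Mitochondrially encoded genes took 1.71% of its gene counts against 0.95 to 1.06% in the others.

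In c-FosDCh DMM replicate 4, Fosl2 was at 8.25 log2 CPM against 7.62 to 7.69 in the other libraries of that label, Jun at 5.86 against 4.91 to 5.07, Tnfaip6 at 4.92 against 2.93 to 3.22 and Apol11a at -1.82 against 0.52 to 0.81. The Wnt list had a mean of 3.78 log2 CPM there against 4.28 to 4.31, and the osteoblast and osteocyte list 5.37 against 6.59 to 6.84. In c-FosDCh DMM replicate 3, Otud5 was at 6.39 against 6.47 to 6.48.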

How the results depend on the processing

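Chosen only after results were seen were the tests with a cartilage score as a covariate and those without 3 pairs of libraries: the 2 richest in muscle RNA, c-FosDCh DMM replicates 3 and 4, and the 2 from the animal with Xist counts. In c-FosWT DMM against contralateral libraries edgeR called 0 genes under every scaling, filter and covariate tried and without any single library, while DESeq2 called 902. The 3 pairs of knees from the same animals were also fitted with the animal as a block: 0 genes passed with a fixed block and 0 with a random block, and 18 lists passed with a fixed block (7 higher, 11 lower) as against 18 without it (8 higher, 10 lower). The fixed block ended the calls of the TCA cycle and skeletal muscle lists and added the osteoclast list as higher and the fibroblast list as lower. The 2 added lists had adjusted p = 0.765 and 0.715 with an estimated correlation in the fit without the block. With the random block limma-voom called 3225 genes between the DMM groups, all 3225 of them also called without it, and 0 in the other comparisons either way.

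Between the DMM groups edgeR called 2616 genes, 1443 with no filter on low counts, 1461 with an absolute log2 fold change of at least 1, and 0 in a fit of these 2 groups alone. It called 0 with the muscle, marrow or cartilage score as a covariate, 0 without c-FosDCh DMM replicates 3 and 4 together and 0 without the animal with Xist counts. DESeq2 called 5358, sharing 2613 with edgeR, and leaving out single libraries of the DMM groups gave 0 to 4626. Other scalings gave 2157 to 2845 and robust = FALSE gave 2706. Fos passed with DESeq2 (0.96) and ranged from 0.76 to 1.22 without single libraries, but was 0.21 with the marrow score and 0.64 with the cartilage score as a covariate, and 0.35 without c-FosDCh DMM replicates 3 and 4 together. In the secondary comparison DESeq2 called 41 genes, and leaving out single libraries gave 0 to 1. There 10 lists passed without c-FosDCh DMM replicates 3 and 4 together, against 23, while between the DMM groups 24 passed, against 20. With an estimated correlation 0 lists passed in each of the 3 comparisons, and with fry 0 passed in c-FosWT DMM against contralateral and 0 in the secondary comparison. Outside the fit of fewer samples, the cause was not tested.

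Values that turned sign were all of genes that did not pass. In c-FosWT DMM against contralateral libraries the cartilage covariate turned Col2a1 to 0.33, Pdk1 to 0.03 and Ldha to 0.20, and Mmp13 was -0.03 without the 2 muscle-rich libraries. Between the DMM groups library totals gave -0.05 for Fosl2 and -0.17 for Adamts5, the marrow covariate -0.15 and -0.44, and the omission of c-FosDCh DMM replicates 3 and 4 together -0.05 and -0.20. The cartilage covariate gave -0.29 for Col2a1, which is itself part of that score, and -0.03 for Adamts5. Without single libraries Fosl2 ranged from -0.03 to 0.21 and Adamts5 from -0.11 to 0.10. In the secondary comparison library totals turned Col2a1 to -0.07, and the marrow covariate gave -0.12 for Fos, -0.13 for Col2a1 and 0.03 for Mmp13. Mmp3 was 0.23 with limma-voom, with or without the random block. Without c-FosDCh DMM replicates 3 and 4 together the values were -0.37 for Fos, -0.06 for Fosl1, -0.43 for Col2a1, -0.26 for Prg4, 0.23 for Mmp13, -0.04 for Pdk1 and -0.00 for Ldha. Without the animal with Xist counts Col2a1 was -0.07. Without single libraries Col2a1 ranged from -0.07 to 0.43, Mmp3 from -0.41 to 0.56 and Mmp13 from -0.71 to 0.04. The cause was not tested. Of 90 named results between the DMM groups, 81 no longer passed with a muscle, marrow or cartilage covariate, and 33 without a filter on low counts, each with its direction kept. Depth limits genes such as Fosl1, at 0.249 CPM in c-FosWT DMM libraries.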

Other observations

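Chosen only after results were seen were the tests of a marrow gradient within groups, of Fos against the marrow score and of the Y-linked genes, as well as the genes and ratios named in the next 2 paragraphs. In lists of other cell types that did not pass as lists, single genes differed between the libraries labelled c-FosDCh and the c-FosWT libraries from DMM knees. Over all tested genes 14.4% were called between these groups. Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, was higher (log2 fold change 2.97 ± 0.67 SE, n = 4 and 3, edgeR adjusted p = 0.0332), as was Alpl, the phosphatase gene of mineralising cells (1.24 ± 0.36, 0.0471). Of the Schwann cell and nerve list, S100b (2.41 ± 0.52), the myelin gene Ncmap (2.55 ± 0.59) and Pmp22 (1.22 ± 0.30) were higher and Mag, a myelin glycoprotein gene (-1.53 ± 0.45), was lower. Mkx, a tendon transcription factor gene (1.23 ± 0.26), and the cartilage and tendon matrix genes Cilp2 (2.30 ± 0.54) and Fmod (1.33 ± 0.33) were higher in the tendon list. The fibroblast list had Gsn, the gelsolin gene (1.51 ± 0.44), and the smooth muscle and pericyte list had the proteoglycan gene Cspg4 (1.2 ± 0.27) higher. As with all calls between these groups, 0 genes remained past the test with the marrow score as a covariate.

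Within the cartilage list 25 of 30 genes had positive values between the DMM groups, with 15 called higher and 0 lower. The sizes differed, however, and 5 genes had negative values. Matn3, a matrilin gene of growth cartilage, had 95.1, 21.5 and 22.7 CPM in c-FosWT DMM libraries and 0.073, 4.07, 0.751 and 0.477 CPM in those labelled c-FosDCh (log2 fold change -5.04 ± 1.67, edgeR adjusted p = 0.0628). In contralateral libraries it ranged from 0.714 to 138 CPM. Matn1 (-2.97 ± 1.13, 0.0867), Epyc (-1.87 ± 0.93, 0.157) and Col9a1 (-1.37 ± 0.80, 0.213) also had negative values, none past the test, while Cilp, the gene of cartilage intermediate layer protein, rose (3.22 ± 0.78, 0.0344). Matn1 had 100, 1 and 9 counts in c-FosWT DMM libraries and 1, 7, 4 and 4 in those labelled c-FosDCh, so its value rests on 1 library. Epyc had 41, 19 and 10 against 5, 8, 8 and 1 counts. The difference log2 Prg4 minus log2 Col2a1 was 0.77 ± 0.78 (SD, n = 4) in libraries labelled c-FosDCh and -1.31 ± 0.22 (n = 3) in c-FosWT DMM libraries, with no overlap (exact permutation p = 0.029, the smallest possible with 35 splits, adjusted p = 0.26). The difference log2 Fos minus log2 Fosb was 0.99 ± 0.35 in libraries labelled c-FosDCh and 2.17 ± 0.40 in c-FosWT DMM libraries (exact permutation p = 0.029, adjusted p = 0.26). Against all 7 c-FosWT libraries, at 1.93 ± 0.35, the exact permutation p was 0.003 (adjusted p = 0.081), but these come from 4 animals and the test takes both knees of an animal as independent. Neither passed the correction over 27 tests.

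A lower share of marrow RNA in the libraries labelled c-FosDCh is a candidate explanation for many of the 2616 genes that differed between the DMM groups. In c-FosDCh DMM replicates 1 and 2 the 2 lists of the score did not fall alike. Their erythroid means of 6.17 and 6.96 log2 CPM lay below the 7.86 to 8.45 of c-FosWT DMM libraries. Granulocyte means of 7.54 and 6.93 stood against 7.12 to 7.99. In replicates 3 and 4 both lists lay below every c-FosWT DMM library. Across the 2609 called genes outside the marrow lists, the fold change followed the slope of each gene on the marrow score within the 4 contralateral libraries. Spearman rho was 0.76 across genes, with 92.2% of signs alike, and 0.60 over all tested genes outside these lists. The marrow scores of contralateral replicates 1 to 4 were 6.66, 5.92, 5.97 and 7.60, so replicate 4 weighed most in these slopes. The abundant marrow genes Hbb-bs and S100a8 had 1270 and 744 CPM against 5150 and 1500 CPM. They belong to the lists of the score and are no separate support. S100a8 was at 1540 CPM in c-FosDCh DMM replicate 1, within the 1340 to 1800 CPM of c-FosWT DMM libraries. With the marrow score as a covariate the median absolute log2 fold change of the called genes went from 1.08 (median SE 0.27) to 0.60 (median SE 0.24) and no call was left, with 2084 genes at an unadjusted p under 0.05; although 0.60 is above 2 such errors, the genes were picked for large values in this very comparison and the score is an imperfect measure, so that bound was no fair one and the size left over cannot be told apart from selection. For the cartilage list 40.0% of the genes (12 of 30) lay more than 2 standard errors from the list median. Values ran from Matn3 at -5.04 to Cilp at 3.22. This argues against even dilution of an unchanged chondrocyte population as the only cause. The test takes all list genes as coming from that population alone. Matn3 ranged from 0.714 to 138 CPM among contralateral libraries, so dilution as part of the change is not settled by it. Loss of Fos in chondrocytes, a change in joint tissue after surgery and differences in dissection stay open.

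Fos was not lower in the libraries labelled c-FosDCh. Marrow cells as the source of the Fos reads are argued against, because Fos fell with the marrow score within groups (slope -0.33 ± 0.09 SE). The immediate early list itself had a mean of 4.77 ± 0.18 log2 CPM in these libraries against 4.20 ± 0.09 in c-FosWT DMM libraries (camera adjusted p = 0.00708, and 0.436 with an estimated correlation). Whether a stronger immediate early response accounts for the Fos level cannot be told. Fos minus the immediate early list differed by 0.30 between the DMM groups, with an SE of 0.37 (exact permutation p = 0.49). This value lies on the side set beforehand as speaking against that account, but within its spread. Reads from a part of Fos that was not deleted, or an incomplete deletion, cannot be told apart from an intact gene either, since the value of 0.98 covers the whole gene and counts per exon were not used here. A wrong genotype label was not tested, and the effect of genotype itself stays open.

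Both libraries of 1 c-FosWT animal held Xist, the RNA of the inactive X chromosome, with 1164 counts (83.1 CPM) in contralateral replicate 2 and 5536 counts (317 CPM) in c-FosWT DMM replicate 2, against 0.219 to 3.89 CPM elsewhere. Y-linked genes were present in both, at 5.72 and 5.37 mean log2 CPM against 5.36 to 5.91 in the other libraries. Female cells mixed into both libraries cannot be told apart from male cells alone by the lower value, 5.37: it is inside that range, which had been named as speaking against a mixture, but the Y-linked genes are so high throughout that losing a small share would be hidden. A second X chromosome cannot be settled either, since 4 genes that escape inactivation were at 6.18 in the contralateral library, inside the 6.14 to 6.35 of the others, and at 6.41 in the DMM library, above it. Apart from the second X chromosome no biological explanation was tested, as the labels give no sex.

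All splits of the compared libraries into groups of the same sizes were fitted in the same way, 35 for each comparison. Of the 35 splits of the DMM libraries 2 gave at least as many genes as the real 2616, the highest other being 3353, when c-FosDCh DMM replicate 2 was grouped with the c-FosWT DMM libraries, so chance was not excluded. In c-FosWT DMM against contralateral libraries and in the secondary comparison all 35 of 35 splits gave 0 genes, the real one and the highest other included. As no split can give fewer than the real 0, these counts say nothing about chance.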
